A study of Oncorhynchus mykiss with 6 samples.

How the data were processed

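Small RNA counts were examined for 6 liver libraries of rainbow trout (Oncorhynchus mykiss), 3 from fish kept at 18 °C (control) and 3 from fish whose water was warmed stepwise to 24 °C (heat), all aged 150 days per the labels. Groups and replicate numbers follow the sample labels. The labels name the tissue as liver and the fish as female, and do not say which or how many fish went into each library. One protocol field speaks of retina and of an rRNA-depleted, fragmented RNA preparation. That text does not describe a small RNA library, so the preparation of these miRNA libraries is not given in the sources used here.

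Per the file headers, each deposited file lists for every miRNA name its length, its sequence, the count in that library, a TPM value and the total over the 6 libraries. The count column held whole numbers, which sum to 9267658 to 12778484 per library, and was used as deposited by the authors. No entry equalled 1, and the smallest count above 0 was 2. The TPM column, scaled by the authors, writes 0.01 where the count is 0 and sums to 1005410 to 1008150, and it was not used in any test. The aligner, the miRNA database, the genome build and the method of prediction are not given in the sources used here. The 2730 names comprise 522 of known miRNA families, which end in x, y or z with no definition in the files, and 2208 predicted miRNAs. They stand for 1685 distinct sequences. A total of 404 sequences appear under more than 1 name, up to 16 names each, and the counts of the names are identical for 90.8% of them. Predicted miRNAs are therefore referred to by sequence. No genome was used here, so positions of the miRNAs were not determined, and the gene table of assembly USDA_OmykA_1.1 was not needed because the files name no genes.

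Counts were tested in R 4.3.3 with edgeR 4.0.16: filterByExpr with a minimum count of 10, TMM normalization, and the robust quasi-likelihood test of heat against control with Benjamini-Hochberg adjustment at 0.05. This kept 651 names (249 known and 402 predicted, or 476 distinct sequences). Standard errors were derived from the log2 fold change and its F statistic, and 95% intervals from the t distribution with the fitted degrees of freedom. Normalized CPM values use the TMM-adjusted library sizes. A second fit summed known names over a family and counted each predicted sequence once. Lists of miRNAs were tested with camera from limma 3.58.1 on voom values with a preset correlation of 0.01 between members, adjusted over the 14 of 17 lists that had at least 3 tested members. Library composition was compared with a two-sided exact permutation test, which cannot give a p under 0.1 for 3 libraries against 3. Intervals for shares are exact binomial 95% intervals and cover counting error only, since reads without molecular identifiers are not independent molecules. Figures were drawn with matplotlib 3.10.9.

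The lists, the tests, the alternatives and the rule for naming miRNAs were set before the data were examined. The rule named up to 10 higher and 10 lower features past the threshold with separated groups or, where fewer than 10 passed, the 10 names with the lowest p. It also named the 5 most abundant tested features and, for every list, up to 3 members with the lowest p. Predicted miRNAs of unknown identity were limited to 2 higher and 2 lower. The lists were hepatocyte, erythrocyte, leukocyte, endothelial and stromal, muscle, pancreas, gonad and embryo, retina and neural, hypoxia- and infection-responsive, p53-responsive, let-7, miR-17/92, miR-30, miR-29, miR-200, miR-10/99/100/125 and lipid-metabolism miRNAs. Lists of host genes, set for the case of circular RNA files, did not apply.

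Alternatives were DESeq2 size factors, library totals alone, the DESeq2 1.42.0 Wald test (on all names, with its own filtering), no count filter, a minimum count of 20, each library left out in turn, a replicate block, and for lists camera with an estimated correlation and fry. Detection was also counted after thinning to the smallest total and with at least 5 reads. Chosen after the data were seen were counting each sequence once, known families alone, limma-voom with library quality weights, edgeR without robust estimation, DESeq2 after the same count filter, and leaving out control replicate 2 and heat replicate 1 together.

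The procedure was tested on simulated counts for the 651 names of this comparison, drawn from the observed means, library sizes and dispersions, with 200 names changed in each of 10 runs. The edgeR test recovered 10.8% of names changed 2-fold, 59.6% of those changed 4-fold, 83.8% of those changed 8-fold and 86.2% of those changed 16-fold, and 3.45% of its calls were false. DESeq2 recovered 14.0%, 65.4%, 89.6% and 94.0% at these fold sizes, with 4.85% of its calls false. These rates hold for 200 changed names of 651. Where fewer names change, the Benjamini-Hochberg adjustment is stricter, so recovery in the real comparison may be lower. In 10 runs without any change, edgeR made 1 call and DESeq2 made 15. A list whose members were all raised 4-fold was called by camera in 10 of 10 runs, with 0 calls of the other lists. Counts were drawn independently for each name, so members did not vary together, nor did names that share a sequence. In the real lists the estimated correlation ran from -0.187 (gonad and embryo) to 0.648 (miR-200). The 4-fold raise was also larger than the real leukocyte median log2 fold change of -0.45. These runs therefore do not show how often camera calls real lists rightly or falsely.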

Results

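Mature miRNAs were counted in the livers of rainbow trout held at 18 °C and of rainbow trout warmed to 24 °C, to find miRNAs that respond to heat stress. There were 3 libraries per group. Total counts were 9692590, 11894384 and 11117223 in control replicates 1 to 3 and 12778484, 9267658 and 10245572 in heat replicates 1 to 3. The labels do not say that the libraries come from separate fish, so p-values measure the spread between these samples, which may be technical.

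The liver profile was dominated by a few families in both groups. miR-122-x, the main miRNA of hepatocytes, took 24.7% ± 5.46 of counts in control and 24.6% ± 1.30 in heat (SD, n = 3, exact permutation p = 1). Its share was lowest in control replicate 2, at 18.5% (exact binomial 95% interval 18.46% to 18.51%). The 10 most abundant names held 75.7% ± 5.90 of counts in control and 77.2% ± 2.93 in heat (SD, n = 3, exact permutation p = 0.8). The share of predicted miRNAs was 0.251% ± 0.0621 in control and 0.262% ± 0.0564 in heat (SD, n = 3, exact permutation p = 0.7). The number of names detected was 1804 ± 239 in control and 1791 ± 319 in heat (SD, n = 3, exact permutation p = 1), and total counts did not separate the groups either (exact permutation p = 1). After adjustment over the 7 composition measures every p was 1, and the test cannot give a p under 0.1.

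Between 24 and 18 °C, no miRNA passed the edgeR test. Of 651 names tested, 0 were called, 20 had an unadjusted p under 0.05 (13 higher and 7 lower at 24 °C) where chance gives 32.55, and the lowest adjusted p was 0.0977. With 1 library left out the count at an unadjusted p under 0.05 ran from 26 of 815 names (without heat replicate 3) to 49 of 713 (without heat replicate 1). These 20 names stand for 10 sequences, 4 higher and 6 lower, as 1 higher sequence has 9 names. DESeq2 called 2 names, both of the predicted sequence TCCATCAGTCATGTGACCTGA, and had 55 of 2724 names at an unadjusted p under 0.05 when run without the count filter. After the count filter it again called 2 names of this sequence, with 38 of 649 at an unadjusted p under 0.05. Without a count filter, edgeR called 23 names of 6 sequences, 3 higher and 20 lower, none of a known family. The heat libraries lay wholly above the controls for 34 names and wholly below for 20, together 8.29% of those tested, against 10% by chance.

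The sequence TCCATCAGTCATGTGACCTGA showed the lowest p. It was counted 11, 48 and 11 times in control replicates 1 to 3 and 754, 129 and 893 times in heat replicates 1 to 3, or 1.86 ± 1.19 against 53.2 ± 40.3 CPM (SD, n = 3). The fitted difference was 28.0-fold, a log2 fold change of 4.81 ± 0.80 (SE, 95% interval 2.98 to 6.64), higher in 3 of 3 heat libraries than in any control. The log2 fold change was 4.09 without heat replicate 3 and 5.48 without control replicate 2. Its adjusted p was 0.0977 with edgeR and 1.01e-09 with DESeq2, and 0.208 in edgeR when each sequence was counted once. Another predicted sequence, TCAGGTCACATGTTCAGGATAA, differed by 2.83-fold (95% interval of the log2 fold change 0.41 to 2.60), at 0.816 ± 0.256 CPM in control and 2.37 ± 0.418 CPM in heat (SD). In the other direction, TGTGGGTTGAATAGATTGACACT had a log2 fold change of -1.84 ± 0.56 and TGTGGACCCTGAGTTTCACCC of -3.14 ± 0.99 and -2.90 ± 1.05 under its 2 names (SE), or -2.87 ± 1.08 when counted once. These latter 3 had an adjusted p of 0.948.

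**Figure D1:**
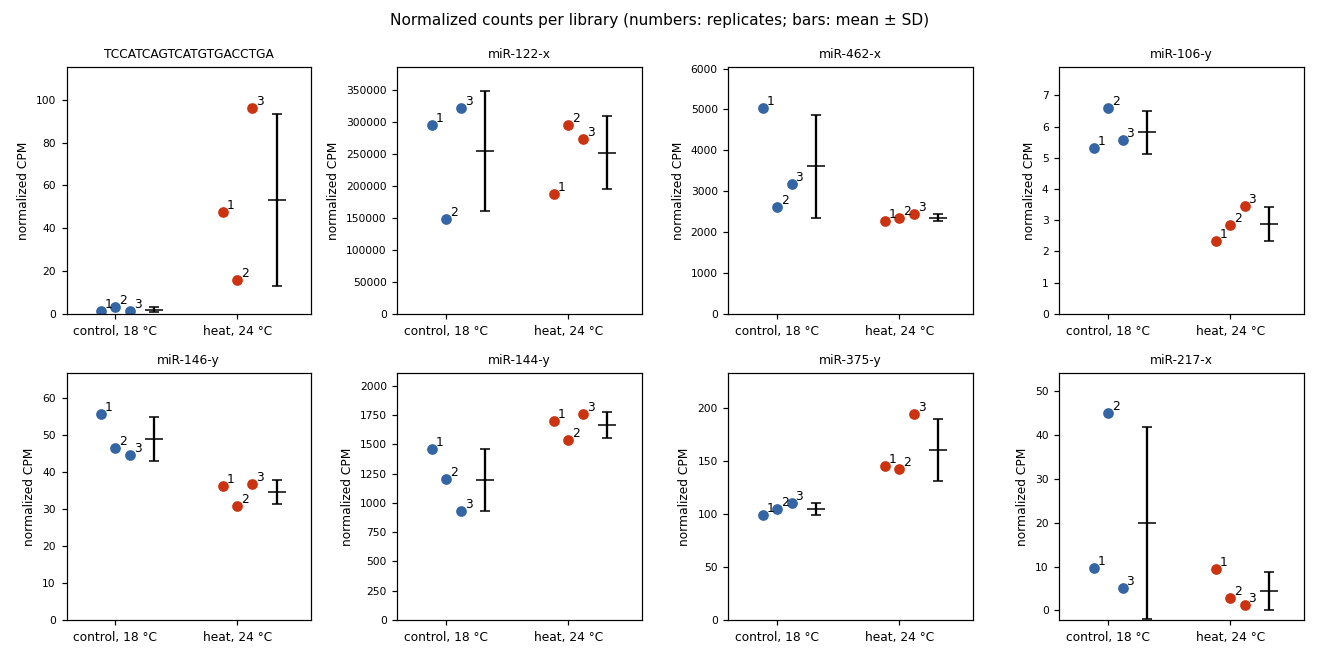
Normalized CPM (vertical axes, from 0 except where an error bar goes lower) of 8 miRNAs in the 3 control libraries at 18 °C (blue) and the 3 heat libraries at 24 °C (red), with replicate numbers and mean ± SD in black. TCCATCAGTCATGTGACCTGA lies at 1.11 to 3.23 CPM in control and at up to 96.0 CPM in heat, where the lowest library (replicate 2) is 4.96-fold above the highest control, while miR-122-x overlaps between the groups and none of the 8 passed the edgeR test.

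None of the 5 most abundant miRNAs passed the edgeR test. miR-122-x had a log2 fold change of -0.02 (95% interval -0.81 to 0.78), miR-100-x of 0.53 (-0.24 to 1.30), miR-199-x of -0.02 (-1.02 to 0.97), miR-26-x of 0.32 (-0.65 to 1.30) and miR-30-x of 0.03 (-0.46 to 0.52). Of the 46 known miRNAs above a log2 CPM of 10, fitted log2 fold changes ran from -0.80 to 0.53, and for 29 the 95% interval excluded a 2-fold change in either direction. Among all known miRNAs the lowest adjusted p was 0.948, and 2 had an unadjusted p under 0.05. These were miR-106-y, of the miR-17/92 group of proliferation-linked clusters, at 5.81 ± 0.681 CPM in control and 2.88 ± 0.552 in heat (SD; log2 fold change -1.02 ± 0.39, SE), and miR-462-y at 14.9 ± 14.4 and 4.41 ± 1.77 CPM (-1.75 ± 0.74). For miR-462-y the value rested on control replicate 2, at 31.3 CPM, without which the log2 fold change was -0.60. Summing names did not add calls: of 404 units (170 families and 234 predicted sequences) edgeR called 0, with 8 at an unadjusted p under 0.05 and a lowest adjusted p of 0.158, and DESeq2 called 1, again TCCATCAGTCATGTGACCTGA.

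Leukocyte miRNAs were the one list past the threshold. All 8 tested members were lower in heat by fitted fold, with a median log2 fold change of -0.45 (camera adjusted p = 0.0203), and the call was lost with adjusted p = 0.746 with an estimated correlation. These members include both the x and the y name of miR-142, miR-146 and miR-223, so they are not 8 independent members. miR-146-y, the less abundant name of miR-146, which is induced in inflammatory signalling, measured 48.9 ± 5.93 CPM in control and 34.7 ± 3.31 in heat (SD). For miR-223-x, the less abundant name of the myeloid miR-223, the values were 1.72 ± 0.309 and 1.14 ± 0.149 CPM. It had 8 to 21 counts per library, against 177 to 1181 for miR-223-y. For miR-155-x, an miRNA of activated immune cells, they were 22.4 ± 10.8 and 14.5 ± 5.18 CPM. The most abundant member, miR-146-x, given here after its values were seen, was at 15050, 30059 and 15452 CPM in control replicates 1 to 3 and 15787, 15787 and 16332 CPM in heat replicates 1 to 3, so its log2 fold change of -0.34 came from control replicate 2. No member passed over all names tested or adjusted over the list alone. The call was also lost when any library except heat replicate 1 was left out, with adjusted p of 0.141, 0.209 and 0.0684 without control replicates 1 to 3 and 0.626 and 0.0828 without heat replicates 2 and 3. The median was -0.45, -0.29 and -0.54 without control replicates 1 to 3 and -0.20 and -0.31 without heat replicates 2 and 3. Leukocyte members were highest in control replicate 2 by median deviation from the other libraries (0.76 in log2, against 0.56 in control replicate 1 and 0.37 in heat replicate 1). Control replicate 3 was at -0.08, heat replicate 2 at -0.82 and heat replicate 3 at -0.15. Heat replicate 1 thus lay above control replicate 3, and the list did not separate the groups library by library.

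The fish-specific miR-462/731 cluster and the hypoxia-responsive miR-210 formed a list in which 5 of 7 members had a fold below 1 and the median log2 fold change was -0.21 (camera adjusted p = 0.131). miR-462-x stood at 3606 ± 1263 CPM in control and 2352 ± 82.1 in heat (SD), lower in 3 of 3 heat libraries than in any control, with a log2 fold change of -0.62 ± 0.28 (SE, adjusted p = 0.995). For miR-731-x the values were 502 ± 74.5 and 383 ± 55.4 CPM.

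Hepatocyte-enriched miRNAs had 8 of 10 members below 1 with a median of -0.11 (camera adjusted p = 0.723). Their lowest-p members had log2 fold changes of -0.62 (miR-194-y), 0.29 (miR-215-x) and -0.39 (miR-122-y), the last of which was 0.12 without control replicate 2 and -1.01 without heat replicate 1. Erythrocyte miRNAs had 3 of 5 below 1 and a median of -0.08 (adjusted p = 0.945). The erythroid miR-144-y measured 1198 ± 264 CPM in control and 1665 ± 114 in heat (SD), higher in 3 of 3 heat libraries than in any control (0.47 ± 0.25, SE, adjusted p = 0.995), while miR-451-x of the same cluster had a log2 fold change of -0.16 and miR-486-x of -2.01 ± 1.06, or -1.08 without control replicate 2. In the endothelial and stromal list 6 of 10 members were above 1. Its median was 0.03 and its mean -0.01 (adjusted p = 0.973, direction down), with -0.35 for miR-199-y, 0.26 for miR-145-x and -0.28 for miR-214-x. Muscle miRNAs had 6 of 6 below 1, with a median of -0.12 (adjusted p = 0.945). Their values were -0.27 for miR-133-z, -0.27 for miR-1-z and -0.17 for miR-206-y, which was 2.01 without control replicate 2.

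Pancreas miRNAs had 2 of 4 members below 1 and a median of -0.22 (adjusted p = 0.945). The islet miR-375-y measured 105 ± 6.01 CPM in control and 161 ± 29.2 in heat (SD), higher in 3 of 3 heat libraries (0.62 ± 0.27, SE, adjusted p = 0.948). The acinar miR-217-x and miR-216-x had log2 fold changes of -2.12 ± 0.98 and -0.76 ± 0.88 (SE), and the list was highest in control replicate 2 (median deviation 1.96 in log2) and heat replicate 1 (0.85). Without control replicate 2, miR-217-x had a log2 fold change of -0.70 and miR-216-x of 0.02, and without heat replicate 1 these were -3.24 and -2.02. The gonad and embryo list had a median of 0.03 and a mean of -0.18 over 3 members (adjusted p = 0.878, direction up), with 0.40 for miR-430-y, -0.98 for miR-202-x (0.29 without control replicate 3) and 0.03 for miR-430-x (1.32 without control replicate 2 and -0.45 without control replicate 1). Retina and neural miRNAs, included because a protocol field speaks of retina, had a median of -0.13 over 10 members (adjusted p = 0.723). Their mean log2 CPM was 3.13 to 3.77 per library, against 11.06 to 11.36 for the hepatocyte list. miR-7-x, miR-96-x and the neuronal miR-124-y had log2 fold changes of -0.53, -0.56 and 0.36, and without control replicate 2 miR-96-x was at 0.28.

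**Figure D2:**
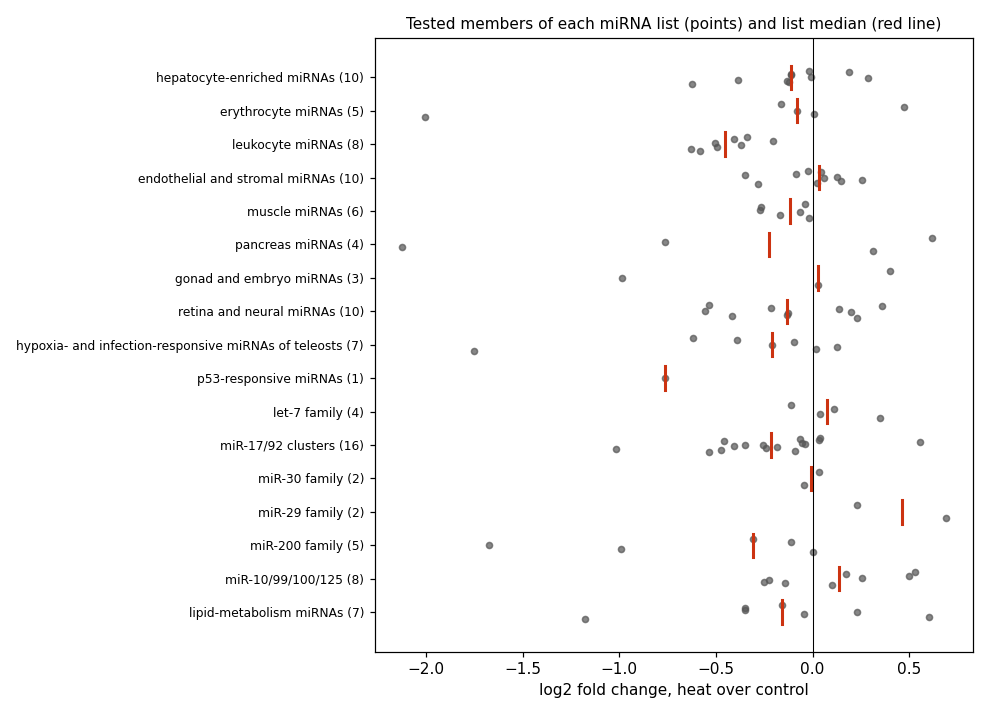
Log2 fold change of heat over control (horizontal axis) of each tested member (points) of the 17 miRNA lists (rows, with the number of tested members), with the list median as a red line. All 8 leukocyte members lie below 0 around a median of -0.45, while the members of the endothelial and stromal list scatter on both sides of a median of 0.03.

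Among the remaining lists, the miR-17/92 clusters had 13 of 16 names (15 sequences) below 1 and a median of -0.21 (adjusted p = 0.257), with miR-19-z at 0.56 and miR-20-y at -0.41 beside miR-106-y. The epithelial miR-200 family had 4 of 5 below 1 and a median of -0.31 (adjusted p = 0.413). Its members miR-200-z, miR-429-y and miR-200-y had log2 fold changes of -1.67 ± 0.85, -0.99 ± 0.77 and -0.31 ± 0.35 (SE), which became 0.02, 0.55 and 0.04 without control replicate 2. Without control replicate 1 this family passed instead (adjusted p = 0.0199, and adjusted p = 0.779 with an estimated correlation). Let-7 miRNAs had a median of 0.07 over 4 members (adjusted p = 0.912), with 0.35 for miR-98-x, -0.11 for let-7-x and 0.11 for let-7-z. The list of miR-10, miR-99, miR-100 and miR-125 had a median of 0.14 over 8 members (adjusted p = 0.723), with 0.50 for miR-99-x and 0.25 for miR-10-x. Lipid-metabolism miRNAs had a median of -0.16 over 7 names of 6 sequences (adjusted p = 0.945), with 0.60 for miR-33-x and -0.35 for both miR-103-y and miR-107-y, which the files list with one and the same sequence. The p53-responsive miR-34-x (-0.76, or -0.03 without control replicate 2), miR-30-x (0.03) and miR-30-y (-0.05), and miR-29-x (0.69, or 1.32 without control replicate 3) and miR-29-y (0.23) belong to lists with too few members for a list test.

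Correlations between libraries overlapped within and between groups. Spearman values across the tested names ran from 0.791 to 0.856 within control, 0.856 to 0.883 within heat and 0.802 to 0.884 between groups. Names are not independent replicates. The highest value (0.884) joined control replicate 2 and heat replicate 1, across temperatures. Both libraries also had TMM factors of 1.25 and 1.24, against 0.87 to 0.92 elsewhere. Their names detected were 2077 and 2157, against 1579 to 1701 elsewhere. Control replicate 2 stood apart: over 131 known miRNAs above a log2 CPM of 5, the SD of its deviations from the other 5 libraries was 0.86 in log2, against 0.42 to 0.50 in the other libraries. The labels do not say how many tanks each temperature had or which tank a library came from, so a tank effect stays open. With a median SE of 0.42 in log2 for known miRNAs, changes near 2-fold were mostly not detectable at this number of libraries.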

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

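Some settings were chosen after the data were seen: limma-voom quality weights, edgeR without robust estimation, DESeq2 after the count filter, each sequence counted once, known families alone, and leaving out control replicate 2 and heat replicate 1 together.

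The count of 0 names called by edgeR held with DESeq2 size factors, library totals alone, a minimum count of 20, the replicate block, each library left out in turn, control replicate 2 and heat replicate 1 left out together, no robust estimation, each sequence counted once and known families alone, and limma-voom with quality weights also called 0. The DESeq2 Wald test called 2 names, both on all names and after the count filter, and edgeR without a count filter called 23. For families and predicted sequences DESeq2 called 1 in both settings and edgeR without a filter 6. The cause was not tested. The log2 fold change of TCCATCAGTCATGTGACCTGA was 4.80 with DESeq2 on all names (adjusted p = 1.01e-09), 4.80 after the count filter (adjusted p = 2.71e-10) and 4.82 without a filter (adjusted p = 8.71e-16), each past the threshold. Over the 6 libraries left out in turn it ranged from 4.09 to 5.48 (adjusted p = 0.0784 to 0.907). Equal replicate numbers did not clearly pair libraries. Same-number correlations of deviations were 0.106, -0.202 and 0.116, and 2 of 6 libraries correlated best with their own number. Each pair needed 0.1 to count as paired, which replicate 2 missed. With so few libraries, this check cannot exclude a pairing. The replicate block gave 0 called names, 33 at an unadjusted p under 0.05, and 0 lists.

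Lists past the threshold numbered 1 with the preset correlation, 0 with an estimated correlation, 0 with fry, 0 without a filter and 0 to 1 when 1 library was left out. The leukocyte median was -0.45 with an estimated correlation (adjusted p = 0.746) and with fry (adjusted p = 0.912), -0.48 without a filter (adjusted p = 0.255) and -0.47 with the replicate block (adjusted p = 0.0527). It ran from -0.68 to -0.20 over libraries left out, where the call held without heat replicate 1 alone (adjusted p = 0.00382). The call also held without control replicate 2 and heat replicate 1 together (adjusted p = 0.0183). With an estimated correlation, camera lost it in both settings (adjusted p = 0.819 and 0.970). The estimated correlation cannot decide the cause, since that setting also raised p where the correlation was near 0, and no other cause was tested.

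Among names at an unadjusted p under 0.05, the share higher in heat ran from 15.4% without heat replicate 3 to 84.8% with the replicate block, was 40.0% with each sequence counted once, and was 100% of 2 with known families alone. Of 50 known miRNAs named, 25 changed sign in at least 1 of 18 settings, 60 of 893 values, and 0 passed the threshold in any. Reversed log2 fold changes were -0.13 (miR-430-x) with library totals alone, 0.014 (miR-122-x) and 0.018 (miR-199-x) without a filter, and 0.029 (miR-122-x), 0.064 (miR-199-x) and 0.27 (miR-206-y) with the replicate block. They were -0.0057 (miR-430-x) with each sequence counted once, and 0.069 (miR-122-x), 0.060 (miR-199-x) and 0.065 (miR-30-y) with known families alone. Quality weights gave 0.11 (miR-451-x), 0.12 (miR-1-z), 0.38 (miR-206-y), 0.15 (miR-96-x), 0.073 (miR-30-y) and 0.099 (miR-429-y). Without control replicate 2 and heat replicate 1 together the values were -0.011 (miR-30-x), 0.30 (miR-451-x), 0.13 (miR-1-z), -0.011 (miR-430-y), 0.077 (miR-7-x), 0.33 (miR-96-x), -0.0011 (miR-124-y), -0.055 (miR-98-x), 0.089 (miR-30-y), 0.23 (miR-429-y), 0.051 (miR-103-y) and 0.051 (miR-107-y). Leaving out 1 library gave ranges of -0.45 to 1.32 (miR-430-x), -0.29 to 0.23 (miR-122-x), -0.37 to 0.23 (miR-199-x), -0.028 to 0.40 (let-7-z), -0.043 to 0.58 (miR-26-x), -1.01 to 0.12 (miR-122-y), -0.28 to 0.14 (miR-451-x), -1.30 to 2.01 (miR-206-y), -2.02 to 0.017 (miR-216-x), -0.93 to 0.28 (miR-96-x), -0.17 to 0.081 (miR-30-y), -2.19 to 0.024 (miR-200-z), -1.46 to 0.55 (miR-429-y), -0.59 to 0.036 (miR-200-y), -0.52 to 0.030 (miR-103-y), -0.52 to 0.030 (miR-107-y), -0.0076 to 0.098 (miR-30-x), -0.53 to 0.055 (miR-133-z), -1.60 to 0.29 (miR-202-x), -0.18 to 0.033 (let-7-x) and -0.056 to 0.72 (miR-430-y). Without a change of sign, miR-462-y ran from -2.14 to -0.60, miR-217-x from -3.24 to -0.70, miR-486-x from -2.53 to -1.08 and miR-34-x from -1.17 to -0.026. The cause was not tested.

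Differences of heat minus control in composition changed sign with the library left out: -196.5 to 123 names detected, -1.85 to 3.75 percentage points for the 10 most abundant names, -0.0203 to 0.0468 for predicted miRNAs and -1144784 to 610629 total counts. Thinning and a minimum of 5 reads kept the sign for names detected. Pseudocounts, filters on normalized values, quantile normalization and recovered reads were planned for normalized files and did not apply, as the files held counts.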

Other observations

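All tests below were chosen after the results were seen, except the count of splits for edgeR and the test of arm ratios.

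Names ending in x and y of 1 family, read here as its arms although the files do not define the endings, gave a way to ask whether temperature shifts which arm is kept. For 75 families with both tested, the log2 ratio of y to x was compared between 24 and 18 °C with limma. It passed for 0 families, with 1 at an unadjusted p under 0.05 (miR-106, -0.94) and a lowest adjusted p of 0.982; no other tool was run. The 95% interval reached 1.08 in log2 to either side of the estimate at the median and farther for other families. The outcome set beforehand for no shift, that no family passes, was met. Intervals this wide can meet it through low power alone, so it was too lenient to exclude a shift. Shifts of arms stay open. The less abundant arm was relatively highest in control replicate 2 and heat replicate 1, by a median of 0.36 and 0.32 in log2 over the other libraries.

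Control replicate 2 differed from the other 5 libraries by more than 2-fold in 29 of 131 known miRNAs, 12 lower and 17 higher, against 2 to 7 in the others. miR-125-x was at 4241 CPM there and 15427 to 33915 CPM elsewhere, and miR-26-x at 22019 and 51047 to 76304. miR-200-z was at 847 and 62.3 to 154 CPM, and miR-2188-x at 4278 and 513 to 1125. Removing a linear trend on GC content and length left the SD of its deviations at 0.83, above the highest other library (0.48). Among the 46 miRNAs above a log2 CPM of 10 the SD was 0.86 (highest other 0.45). Neither a linear trend on GC content and length nor counting noise of low miRNAs therefore accounts for it. Other effects of base composition were not tested. Other tissue or a lower share of hepatocytes could contribute and cannot be told apart from a difference between fish, which was not tested. Only 1 abundant miRNA (miR-125-x) lay below miR-122-x by more than 0.5 beyond the other libraries, where at least 3 were needed to exclude dilution. The lists of other cell types had medians from -0.10 (endothelial and stromal) to 1.96 (pancreas), the lowest within its spread of 0. The hepatocyte list was at 0.09 with 5 of 10 members higher. Its main member miR-122-x was lowest in control replicate 2, at 147764 CPM against 187010 to 321415 CPM elsewhere. In contrast, miR-122-y and miR-194-y were higher there, by 1.25 and 1.33 in log2. The hepatocyte miRNAs therefore do not decide whether the share of hepatocytes was lower.

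The sequence TCCATCAGTCATGTGACCTGA had 96.2% of its reads in the heat libraries. Its longest stretch in common with any other listed sequence on the same strand was 10 of 21 bases, which argues against reads of another listed miRNA. The lowest heat library exceeded the highest control by 4.96-fold in CPM, beyond the largest ratio of library totals (1.38). CPM is already scaled to library size, so this ratio cannot test depth. In raw counts, heat replicate 2 had the smallest total (9267658) yet counted the sequence 129 times, against at most 48 in control. These raw counts argue against depth. Leaving out 1 library at a time moved the adjusted p of the sequence in edgeR between 0.0784 and 0.907. An induction by heat, a tank effect and carry-over of a sequence not listed stay open. No partner arm is listed, but partners were searched by name only. The end of the sequence is complementary to the start of another predicted sequence, at 0.816 CPM in control and 2.37 CPM in heat. That other sequence was also higher in 3 of 3 heat libraries than in any control. Both were picked among the 10 names with the lowest p, so this separation is no evidence of a shared origin. The names of both sequences end in 3p. Pairing between them was not tested, so an origin from a miRNA hairpin stays open.

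Whether the lower leukocyte miRNAs in heat reflect members that vary together between fish, whatever the temperature, stays open. By median deviation in log2, the list ran from -0.08 to 0.76 in control and from -0.82 to 0.37 in heat. It therefore varied within each temperature too, and the groups overlapped. With a correlation estimated from the libraries (0.223) the camera adjusted p was 0.746. That setting cannot decide, since it raises p even where the correlation is near 0. For the hypoxia- and infection-responsive list without heat replicate 3 (estimated correlation -0.011), the camera p went from 0.0195 to 0.0951. A smaller share or altered state of leukocytes at 24 °C stays open and was not tested.

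With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 0 names with edgeR (as many or more in 10 of 10 splits) and the highest other 1; 0 families or predicted sequences (10 of 10) and the highest other 1; 2 names with DESeq2 on all names (4 of 10) and the highest other 24; and 1 list (3 of 10) and the highest other 2. The split that put control replicates 1 and 2 with heat replicate 1 gave the 24 DESeq2 names and the 2 lists, several times the real count of names, but 1 name with edgeR. It may point to a structure of the libraries other than temperature, which was not tested.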
